A study of Mus musculus with 13 samples.

How the data were processed

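RNA of haematopoietic stem cells (HSCs) from untreated C57BL/6 JRj mice was sequenced in 13 libraries. Per the labels' protocols, marrow was enriched for Kit, live HSCs were sorted as lineage-negative, Kit-positive, Sca1-positive, CD48-negative and CD150-positive cells, and libraries were made with a Nextera XT kit in volumes reduced 20-fold. The sorted HSCs were divided by mitochondrial membrane potential (MMP) into MMP high and MMP low cells. The dye and the gates for MMP are not given in the sources used here. Young mice were 8 to 12 weeks old and old mice over 18 months. The labels do not say whether replicates of a group are separate animals, so the p-values measure only the spread between samples, which may be technical.

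The deposited files hold raw counts per gene symbol, whole numbers with no header, for 43280 symbols in each library. Trim Galore, STAR 2.7 and the build GRCm38 are named per the submitters' processing notes. The counting tool, its strand setting and the annotation are not given in the sources used here. Even counts made up 51.2% to 53.8% of counts from 1 to 100, as if both mates of a pair were often counted. A count may therefore stand for less than 1 fragment, and PCR copies cannot be told from separate molecules. All 37 symbols of the mitochondrial genome had a count of 0 in every library, so the list of mitochondrially encoded genes could not be tested. Gene positions come from GENCODE mouse release M21 on GRCm38, in which 39379 of the symbols matched once. A few symbols are older names without a match (Tenc1, Ptplad2 and Sdpr) or are named differently in other annotations (Clca1 and Clca2), and no position is given for these.

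Total counts per library ran from 8537834 to 10574730, and 18502 to 26063 symbols had a count. Counts were analysed with R 4.3.3 and edgeR 4.0.16. Low counts were removed by filterByExpr with the groups given (minimum count 10, minimum total 15), which kept 17125 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion (glmQLFit, glmQLFTest) was fitted to all 13 libraries with a mean for each of the 4 groups, leaving 9 residual degrees of freedom. The common biological coefficient of variation was 0.413. The contrasts were MMP high against low in young and in old HSCs, old against young in MMP low and in MMP high HSCs, the averages of both pairs, and the interaction of age and MMP. Tests are two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p of 0.05. Levels are in CPM (counts scaled to a common library size), log2 CPM values use a prior count of 2, and errors of log2 fold changes are standard errors (SE).

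A set of 34 gene lists with 934 genes, of which 893 were tested, was written down before the data were examined, as were the contrasts, the tests and the rule for named genes. The lists cover mitochondrial functions, metabolism, HSC identity and quiescence, HSC ageing, lineage priming, the cell cycle, gene expression machinery, stress and immune responses, and markers of other marrow cells. The list of HSC identity and quiescence genes is called the identity list below. A change in it does not tell identity from quiescence. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. A list's p-values are adjusted over the lists of a contrast. Where a list's called members are counted in the text, the count adjusted over the list alone is given too. Named genes are up to 10 in each direction with the smallest p among those called, leaving out predicted genes (up to 5 in the averaged contrasts and the interaction). If fewer than 4 were called in a direction, the genes of smallest p make up 4. Added to these are 2 to 4 members of each list described (called members first, then the most abundant), and the genes of the sort gate and of dye efflux.

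Replicate numbers were checked for pairing by correlating the residuals of MMP low and MMP high libraries of the same age and number. The correlations were 0.291, 0.271 and 0.136 in old HSCs and -0.0312, -0.153 and -0.227 in young HSCs. Libraries with neighbouring names are the same pairs in old HSCs, and in young HSCs they are other pairs, with correlations of 0.0822, 0.187 and 0.243. The numbers thus went with positive correlations in the old libraries but not in the young ones. Libraries of different ages, which cannot share an animal, reached 0.284 (Young MMP low 1 with Old MMP low 1) and 0.286 (Young MMP high 1 with Old MMP high 1). Pairing of the old libraries is therefore possible but not established, and old libraries of the same number are called old pairs below. A fit with a block for neighbouring names is given beside the young MMP contrast, and a fit with a block for the old pairs is given beside the old MMP contrast. Library names fall into a series of 5 and a series of 8 libraries, whose meaning the labels do not state, and values within each series are given for the main lists.

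Alternatives set in advance were DESeq2 size factors for the scaling, no filter on low counts, DESeq2 1.42.0 (Wald test), limma voom with quality weights, fits of only the compared groups, a replicate block, a block for neighbouring library names, a series term and leaving out each library in turn. Added after the data were seen were a covariate for transcripts of granulocytes and monocytes, a fit without 2 doubted libraries together (Young MMP low 1 and Young MMP high 4) and a block for the old pairs alone. Distances of old libraries to the mean of young libraries were compared by an exact permutation test and, after the data were seen, by an exact sign-flip test within the old pairs, over ageing genes alone and against young libraries of the same MMP. The fit was tested on simulated data in which 100 of 17125 genes were changed by each fold. Genes were drawn independently with edgeR's own dispersions, so correlated genes, carry-over, pairs and outlying libraries were not tried. Of genes changed 4-fold it recovered 50.0% in the young MMP contrast, 57.0% in the old one, 56.0% and 54.0% in the age contrasts of MMP low and high, 72.0% and 70.0% in the averaged MMP and age contrasts, and 28.0% in the interaction. Of genes changed 2-fold it recovered 11.0%, 5.0%, 9.0%, 10.0%, 47.0%, 33.0% and 1.0% in the same order. Wrong calls were 1 of 62, 4 of 66, 6 of 71, 2 of 66, 3 of 122, 10 of 113 and 1 of 30. Results on a few items withheld for evaluation are left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.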

Results

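The data are counts per gene from 13 RNA libraries of sorted mouse HSCs, the self-renewing cells at the top of blood formation. There were 3 libraries of young MMP low HSCs, 4 of young MMP high, 3 of old MMP low and 3 of old MMP high. Total counts were 9564195, 9643523 and 9351641 in Young MMP low 1 to 3, and 9559719, 10041109, 9125079 and 9116897 in Young MMP high 1 to 4. They were 10574730, 9547895 and 9377026 in Old MMP low 1 to 3, and 9642498, 9307185 and 8537834 in Old MMP high 1 to 3. The series asks how HSCs of high and low membrane potential differ in young and in old mice, and how old HSCs of each kind compare with young ones.

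Transcripts of mature blood cells, which the sort gate should exclude, varied widely between libraries of 1 group. Ngp, a neutrophil granule gene, took from 0.0322% of the counts in Young MMP high 4 to 0.942% in Old MMP low 1. The first component of log2 CPM held 22.0% of the variance, and Young MMP high 4 lay at its far end. Young MMP low 1 had 1218 counts of the nuclear RNA Malat1, against 6055 to 17354 in the other libraries. Young MMP low 3 lay at the far end of the second component (15.9% of the variance) and had the fewest symbols with a count, 18502. It was kept in the fit without 2 doubted libraries.

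**Figure D1:**
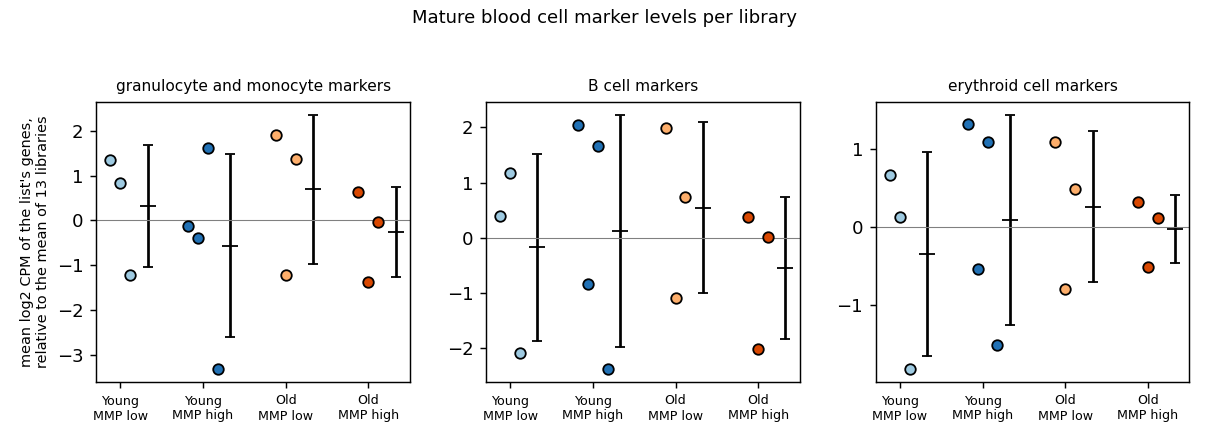
Mean log2 CPM of the genes of 3 marker lists of mature blood cells, relative to the mean of the 13 libraries (vertical axis), in each library (points) of the 4 groups, with the group mean and SD to their right. Granulocyte and monocyte markers range from -3.33 in Young MMP high 4 to 1.92 in Old MMP low 1.

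In young HSCs, DNA replication genes were higher in MMP high than in MMP low cells, and genes of HSC identity and quiescence were lower. Uhrf1, which keeps DNA methylation through replication, went from 48.5 CPM to 154 CPM, a log2 fold change of 1.66 ± 0.25 (SE, n = 4 against 3; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0133). Sult1a1, a sulfotransferase, fell from 55.4 to 9.13 CPM (log2 -2.60 ± 0.31, adjusted p = 0.00387). Ache, the acetylcholinesterase gene, rose from 5.40 ± 2.44 to 33.0 ± 8.16 CPM (SD; 6.09-fold, adjusted p = 0.00797). In all, 170 of 17125 genes were called, 76 higher and 94 lower in MMP high HSCs.

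The other higher genes of smallest p were Cchcr1 (3.22 ± 0.44), the DNA helicase Brip1 (2.15 ± 0.30), the condensin subunit Ncapd2 (1.41 ± 0.21), the tubulin Tuba8 (1.48 ± 0.22), Aarsd1 (1.41 ± 0.22), the single-strand binding protein Rpa2 (0.87 ± 0.15), the origin licensing factor Cdt1 (1.17 ± 0.20) and the platelet receptor subunit Gp1bb (1.53 ± 0.26), with adjusted p from 0.00825 to 0.0216. Uhrf1 lies on chromosome 17 from 56303321 to 56323486, Brip1 on chromosome 11 from 86058138 to 86201193, and Cdt1 on chromosome 8 from 122568015 to 122573554. Each of these 10 genes was higher in all 4 MMP high libraries than in the 3 MMP low libraries. The lower genes were the interferon-inducible GTPases Gbp4 (-2.52 ± 0.29), Gbp8 (-2.07 ± 0.24) and Gbp6 (-2.11 ± 0.30), Dennd1c (-1.28 ± 0.16), Smtnl1 (-4.91 ± 0.63), Enpp5 (-1.59 ± 0.22), Tenc1 (-2.09 ± 0.29), Ptplad2 (-1.12 ± 0.17) and Ifitm1 (-1.26 ± 0.19), with adjusted p from 0.00387 to 0.0133. Sult1a1 lies on chromosome 7 from 126672865 to 126676432 and Ifitm1 on chromosome 7 from 140967221 to 140969825. Gbp4, Gbp6 and Gbp8 are close relatives whose reads may be shared, and Gbp4 and Gbp8 overlap in the annotation. Reads of Aarsd1, Cchcr1 and Tuba8 may likewise be shared with overlapping or related genes. Of the sort gate genes, Slamf1 (CD150) fell by 0.94 on the log2 scale (SE 0.17, adjusted p = 0.0249) and Ly6a (Sca1) fell by 1.33 (SE 0.26, adjusted p = 0.0322). Both missed the threshold without any 1 of Young MMP low 1 and 3 and Young MMP high 1, 2 and 3 (Ly6a also without Old MMP high 1 or 2), with adjusted p up to 0.111. Kit was at -0.29 ± 0.17 (adjusted p = 0.476) and Cd48 at 0.19 ± 0.70 (adjusted p = 0.937). The dye efflux genes Abcb1a (adjusted p = 0.619), Abcb1b (0.937) and Abcg2 (-0.59 ± 0.16, 0.101) were not called.

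Of 35 replication and S phase genes, 15 rose and none fell (31 adjusted over the list alone; median log2 0.872; camera adjusted p = 1.41e-30, and adjusted p = 0.0279 with an estimated correlation). Fen1, a flap nuclease, was at 1.20. Of 36 G2 and mitosis genes, Nek2 (1.81) and Bub1b (1.28) rose, 14 when adjusted over the list alone. The median was 0.851 (camera adjusted p = 1.09e-16, but adjusted p = 0.189 with an estimated correlation). Of 35 HSC identity and quiescence genes, 9 fell, among them Sult1a1, Ifitm1, Ndn (-1.29) and Pdzk1ip1 (from 240 to 120 CPM). Adjusted over the list alone, 1 was higher and 19 were lower (median -0.777, camera adjusted p = 8.59e-16, and adjusted p = 0.0279 with an estimated correlation). Of 47 genes reported higher with HSC ageing, 6 fell, including Enpp5, Tm4sf1 (-3.78), Cpne8 (-1.58) and Slamf1. Adjusted over the list alone, 1 was higher and 13 were lower (median -0.592, camera adjusted p = 2.13e-07, and adjusted p = 0.0417 with an estimated correlation). The megakaryocyte genes Gp1bb, Gp5 (1.34), Itga2b (1.70) and Pf4 (2.36) rose, of 23 measured. Adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 0.00741, but adjusted p = 0.331 with an estimated correlation, and 0.0580 by camera without Young MMP low 2). Of the 70 respiratory chain and ATP synthase genes no member was called, though 67 had a fold change above 0 (median 0.316, camera adjusted p = 8.29e-10, but adjusted p = 0.339 with an estimated correlation). Genes of mitochondrial biogenesis and import, of which none were called, had a median of 0.236 over 32 (camera adjusted p = 0.00316, and adjusted p = 0.0417 with an estimated correlation). Interferon response genes had a median of -0.335 with none called, 6 lower adjusted over the list alone (camera adjusted p = 3.31e-05, but adjusted p = 0.0741 with an estimated correlation). Without Young MMP low 3, Young MMP high 1 or Young MMP high 2, each of Fen1, Nek2, Bub1b, Ndn, Pdzk1ip1, Tm4sf1, Cpne8, Slamf1, Gp1bb, Gp5, Itga2b and Pf4 missed the threshold over all genes. Several did so without other libraries too (adjusted p up to 0.160 for Bub1b). Granulocyte and monocyte markers, whose levels varied between libraries, moved the same way as the identity genes (median -0.617, camera adjusted p = 0.0135, but adjusted p = 0.666 with an estimated correlation, and 0.239, 0.0580 and 0.430 by camera without Young MMP low 1, Young MMP low 2 and Young MMP high 4). The 7 stromal and endothelial markers also lay below 0 (median -1.62, none called, 4 lower adjusted over the list alone; camera adjusted p = 0.00291, but adjusted p = 0.114 with an estimated correlation).

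The number of calls depended on single libraries: it was 11 without Young MMP low 3, 22, 24, 59 and 275 without Young MMP high 1, 2, 3 and 4, 100 without Old MMP low 1, and 86, 73 and 82 without Old MMP high 1, 2 and 3. With a block for neighbouring library names 117 genes were called, of which 68 were also called without it. In a fit of the young libraries alone, edgeR called 0 genes, 1870 at an unadjusted p of 0.05. Without Young MMP low 3, Uhrf1, Brip1, Ncapd2, Tuba8, Aarsd1, Ptplad2 and Ifitm1 were at an adjusted p of 0.0694 and Rpa2, Cdt1 and Gp1bb at 0.0898. Rpa2, Cdt1, Gp1bb, Ptplad2 or Ifitm1 also missed the threshold without Young MMP high 1 or 2, as did Gp1bb without Young MMP low 2 or Young MMP high 3 (adjusted p from 0.0510 to 0.0736).

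**Figure D2:**
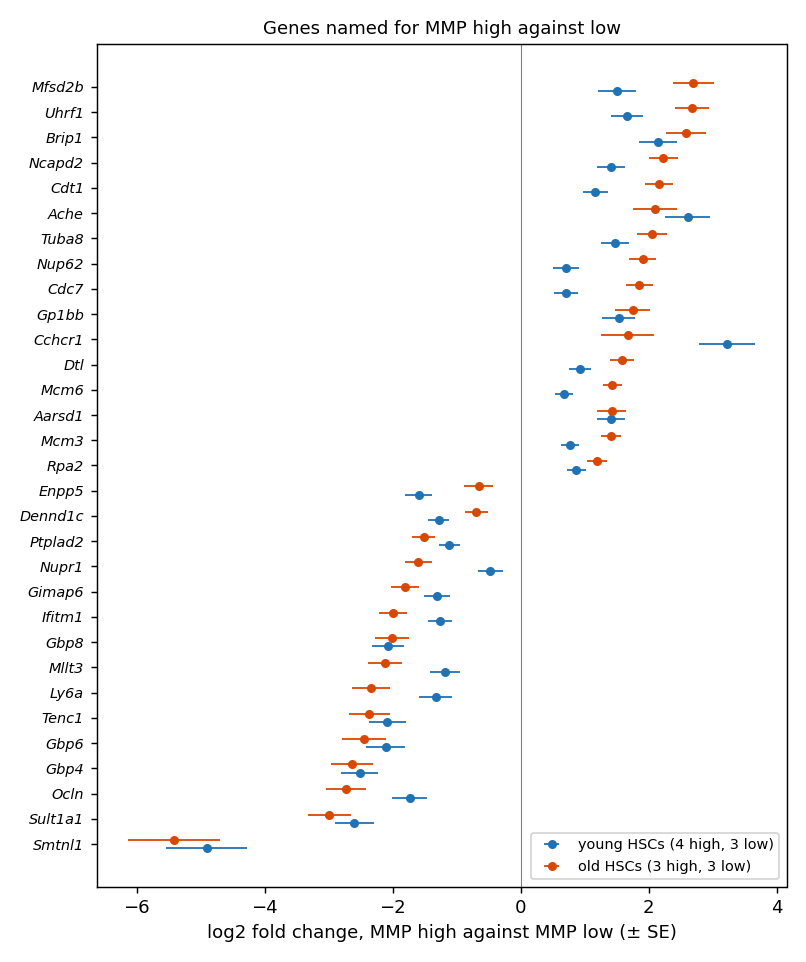
Log2 fold change of MMP high against low HSCs with its SE (horizontal axis) for named genes (vertical axis) in young (7 libraries) and old (6 libraries) mice. Uhrf1 is at 1.66 in young and 2.68 in old HSCs, and Sult1a1 at -2.60 and -2.99.

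In old HSCs, genes of DNA replication were higher in MMP high than in MMP low cells. Genes of HSC identity and quiescence, and of HSC ageing, were lower. Mcm6, a subunit of the replicative helicase, rose from 319 to 860 CPM (log2 1.43 ± 0.15, n = 3 against 3; edgeR adjusted p = 0.000623), and Uhrf1 rose by 2.68 ± 0.27 (adjusted p = 0.000623). Sult1a1 fell from 251 to 31.7 CPM (log2 -2.99 ± 0.34, adjusted p = 0.000741), and Ly6a, a marker of the gate, was at -2.34 ± 0.29 (adjusted p = 0.00105). In all, 627 genes were called, 381 higher and 246 lower. With a block for the old pairs 589 were called, 369 higher and 220 lower, of which 518 were also called without it.

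The other higher genes were Cdt1 (2.16 ± 0.22), Ncapd2 (2.23 ± 0.23), the helicase subunit Mcm3 (1.41 ± 0.15), the replication kinase Cdc7 (1.86 ± 0.21), the nucleoporin Nup62 (1.91 ± 0.21), Tuba8 (2.06 ± 0.24), Dtl (1.58 ± 0.19), which directs Cdt1 to degradation, and the lipid transporter Mfsd2b (6.50-fold, from 20.3 to 132 CPM). Mcm6 lies on chromosome 1 from 128331590 to 128359664. The other lower genes were Ifitm1 (from 692 to 174 CPM), the tight junction gene Ocln (-2.72 ± 0.31), Ptplad2 (-1.52 ± 0.18), Gbp4 (-2.63 ± 0.32), Mllt3 (-2.12 ± 0.26), Gimap6 (-1.81 ± 0.22), the stress-induced regulator Nupr1 (-1.60 ± 0.21) and Smtnl1 (-5.42 ± 0.72). Each of these genes was higher, or lower, in 3 of 3 MMP high libraries than in all MMP low libraries, and their adjusted p ranged from 0.000623 to 0.0013. Slamf1 fell by 0.98 (SE 0.18, adjusted p = 0.00841, but 0.0716 without Old MMP high 3), while Kit (-0.12, adjusted p = 0.803) and Cd48 (-0.47 ± 0.76, adjusted p = 0.821) were not called. Neither were Abcb1a (-0.59, adjusted p = 0.610), Abcb1b (-0.34, 0.578) and Abcg2 (-0.37, 0.298).

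Of 35 replication and S phase genes 29 rose (34 adjusted over the list alone; median 1.41, camera adjusted p = 1.22e-44, and adjusted p = 0.00758 with an estimated correlation). Of 36 G2 and mitosis genes 15 rose, among them Nek2 (2.57), Aurkb (2.35), Bub1b (2.06) and Kif23 (1.37), and 32 rose adjusted over the list alone. Their median was 1.46 (camera adjusted p = 2.89e-28, but adjusted p = 0.102 with an estimated correlation). Of 35 HSC identity genes 12 fell, and adjusted over the list alone 1 was higher and 19 lower (median -0.827, camera adjusted p = 1.24e-13, and adjusted p = 0.0223 with an estimated correlation). Of 47 ageing genes 11 fell, including Mllt3, Nupr1, Lpar6 (-1.64) and Cd38 (-1.92). Adjusted over the list alone, 22 were lower (median -1.05, camera adjusted p = 2.63e-16, and adjusted p = 0.00704 with an estimated correlation). Of 19 genes reported lower with ageing 2 rose, among them the nuclear lamina gene Lmnb1 (2.20). There were 5 higher adjusted over the list alone (camera adjusted p = 0.00215, but adjusted p = 0.269 with an estimated correlation, and 0.1 by camera without Old MMP low 2). The megakaryocyte genes Gp5 (1.69), Gp1bb (1.75), Itga2b (2.11) and Pf4 (2.09) rose, of 23. There were 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000917, but adjusted p = 0.270 with an estimated correlation). Interferon response genes Ifi44 (-2.03), Oasl2 (-1.10), Rtp4 (-1.61) and Gbp2 (-1.32) were among 6 of 35 that fell. Adjusted over the list alone, 2 were higher and 13 lower (median -0.661, camera adjusted p = 6.57e-06, but adjusted p = 0.0528 with an estimated correlation). In mitochondria, Timm50 (1.17) and Phb2 (0.61) of the 32 biogenesis and import genes rose, 5 adjusted over the list alone (median 0.238, camera adjusted p = 0.00210, and adjusted p = 0.0280 with an estimated correlation). Phb2, Pf4, Ifi44, Oasl2, Rtp4 and Gbp2 missed the threshold over all genes without Old MMP high 3 and without at least 1 more library (adjusted p up to 0.190 for Phb2). The 70 respiratory chain genes had a median of 0.0667 (camera adjusted p = 0.0964). This hung on single libraries, with medians from -0.0451 to 0.280 when 1 was left out. The list passed by camera without Old MMP high 2 (0.280, adjusted p = 1.73e-05), Old MMP low 1 (0.166, 0.000863) or Young MMP low 1 (0.0573, 0.0437). Granulocyte and monocyte markers were also lower (median -1.13, camera adjusted p = 0.0378, but adjusted p = 0.787 with an estimated correlation, and 0.503, 0.260 and 0.298 by camera without Old MMP low 1, Old MMP low 3 and Old MMP high 2).

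The count of calls was 315 and 246 without Old MMP low 1 and 2, and 410, 254 and 223 without Old MMP high 1, 2 and 3.

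**Figure D3:**
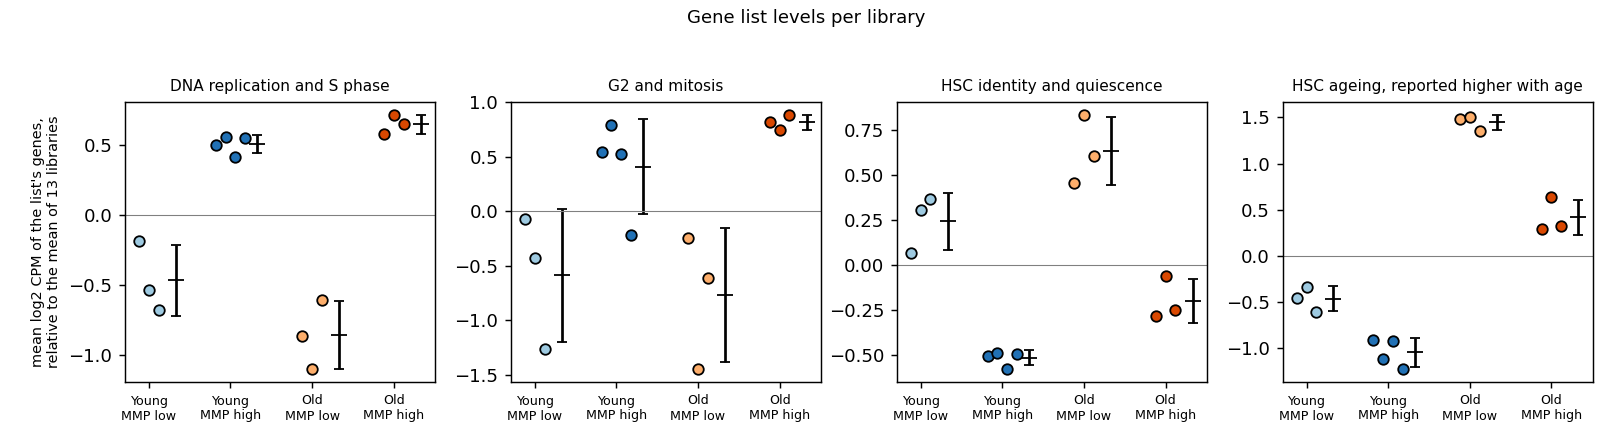
Mean log2 CPM of the genes of 4 lists, relative to the mean of the 13 libraries (vertical axis), in each library (points) of the 4 groups, with the group mean and SD to their right. In both ages all MMP high libraries lie above all MMP low libraries for replication genes. They lie below them for HSC identity and quiescence genes.

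The MMP fold changes of young and old HSCs rest on separate libraries, and across the 17125 genes they correlated with a Pearson r of 0.377 and a Spearman rho of 0.449 (genes are not independent replicates). Of the genes called in either age, 124 were called in both, 66 higher and 58 lower, all in the same direction. If calls were independent and every gene equally likely to be called, 1.69 and 1.35 would overlap. Both contrasts come from 1 fit that shares each gene's dispersion, so the calls are not independent and the overlap without a shared effect may be larger. Of the 627 called in old HSCs, 612 had the same sign in young HSCs, with a median size of 1.34 in old and 0.762 in young HSCs. These genes were chosen by their values in old HSCs, which raises the old median, so the 2 sizes do not show a larger effect with age. Of the 170 called in young HSCs, 169 had the same sign in old HSCs. The r was between 0.136 (without Young MMP low 2) and 0.400 when 1 library was left out. Within the smaller and the larger library series, the difference of the replication score was 0.712 and 1.10 in young and 1.45 and 1.54 in old HSCs, and that of the identity score -0.560 and -0.871 in young and -0.743 and -0.875 in old HSCs. The smaller series holds only 2 MMP high against 1 MMP low library in young and 1 against 1 in old HSCs, so its values have no spread of their own.

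Among MMP low HSCs, the question is how ageing changed them. Genes known from HSC ageing were higher in old cells. Selp, the adhesion receptor P-selectin on chromosome 1 from 164115264 to 164150026, rose from 33.0 to 367 CPM (log2 3.47 ± 0.36, n = 3 against 3; edgeR adjusted p = 0.000868). Nupr1 rose from 30.6 to 193 CPM (2.66 ± 0.22, adjusted p = 0.000123), and Sbspon from 0.391 to 67.1 CPM (7.36 ± 0.78, adjusted p = 0.000868). In all 30 genes were called, 25 higher and 5 lower. Clca1 (3.28 ± 0.36), the scramblase Plscr2 (3.16 ± 0.36), Clca2 (3.83 ± 0.46), the metallothionein Mt2 (5.79 ± 0.82), the glutathione transferase Gstm2 (1.98 ± 0.29), the caveola gene Sdpr (1.75 ± 0.26) and Sult1a1 (2.18 ± 0.32) also rose, with adjusted p from 0.000876 to 0.0111, in all 3 old libraries. The 5 lower genes were Rps4l (-2.30 ± 0.24, adjusted p = 0.000868), Rnase6 (-2.13 ± 0.31, 0.0101), Ctla2a (-1.26 ± 0.22, 0.0390), Phgdh (-0.72 ± 0.13, 0.0390), of serine synthesis, and the cytokine subunit Ebi3 (-1.39 ± 0.25, 0.0408). Rps4l has a close relative that may share its reads. Clca1 and Clca2 follow the file's symbols.

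Of 47 ageing genes 11 rose and 36 adjusted over the list alone (median 1.55, camera adjusted p = 1.75e-46, and adjusted p = 9.51e-05 with an estimated correlation). The list was compiled from knowledge of earlier HSC studies. Of 35 replication genes none were called, and 11 were lower adjusted over the list alone (median -0.445, camera adjusted p = 1.35e-12, but adjusted p = 0.342 with an estimated correlation). Mcm6 was at -0.73 (adjusted p = 0.0938). Of 35 identity genes, Sult1a1 and Mycn (1.26) rose, 5 adjusted over the list alone (median 0.254, camera adjusted p = 0.000165, but adjusted p = 0.393 with an estimated correlation). The count of calls was 17 without Young MMP low 1 or 3, 18, 10 and 16 without Old MMP low 1, 2 and 3, 46 without Young MMP high 4, and 18, 18 and 17 without Old MMP high 1, 2 and 3. Without Old MMP low 2, Gstm2 (adjusted p = 0.0509), Sdpr (0.0671), Sult1a1 (0.0717), Rnase6 (0.0757), Ctla2a (0.176), Phgdh (0.242), Ebi3 (0.291) and Mycn were not called, and Ctla2a, Phgdh, Ebi3 and Mycn (adjusted p up to 0.189) were also lost without most other libraries. Sdpr was also lost without Young MMP low 3 (0.0638), Sult1a1 without Young MMP low 2 (0.0502) or 3 (0.0650), and Rnase6 without Old MMP low 3 (0.0796).

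In MMP high HSCs, ageing genes were higher in old cells too. Plscr2 rose by 3.58 ± 0.34 (n = 3 against 4; edgeR adjusted p = 0.000704) and Selp by 3.05 ± 0.32 (adjusted p = 0.00149). Clca1 (2.62 ± 0.31), Enpp5 (1.77 ± 0.22), the chaperone Clu (2.81 ± 0.35), Nupr1 (1.53 ± 0.19) and Gstm2 (2.08 ± 0.26) rose with an adjusted p of 0.00379 each. Aldh1a1, a retinaldehyde dehydrogenase (1.72 ± 0.25), the GTPase Rhoj (2.18 ± 0.31) and the transporter Abca4 (2.52 ± 0.36) rose with an adjusted p of 0.0116. Each was higher in 3 of 3 old libraries than in all young ones. In all 25 genes were called, 23 higher and 2 lower: Ebi3 (-1.64 ± 0.24, adjusted p = 0.0119) and Slc24a5 (-3.13 ± 0.54, 0.0389). Next by p were Plxdc2 (-1.53 ± 0.28, adjusted p = 0.0539) and Ctla2a (from 1775 to 887 CPM, 0.0954).

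Of 47 ageing genes 9 rose and 28 adjusted over the list alone (median 1.14, camera adjusted p = 1.26e-30, and adjusted p = 0.000527 with an estimated correlation). Of 70 respiratory chain genes none were called and 5 had a fold change above 0 (median -0.355, camera adjusted p = 1.73e-16, but adjusted p = 0.326 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.432 (camera adjusted p = 7.66e-24, but adjusted p = 0.326 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.162 (camera adjusted p = 1.62e-06, but adjusted p = 0.326 with an estimated correlation). G2 and mitosis genes had a median of 0.350 (camera adjusted p = 3.68e-05, but adjusted p = 0.604 with an estimated correlation and 0.0645 by camera without Young MMP high 4). The 7 stromal and endothelial markers had a median of 1.13, with none called and 2 higher adjusted over the list alone (camera adjusted p = 0.0399, but adjusted p = 0.326 with an estimated correlation). By camera they were lost without any 1 of 8 libraries, with adjusted p up to 0.171 without Old MMP high 1. The age contrasts in MMP low and MMP high HSCs shared 15 called genes, 14 higher and 1 lower. The count of calls was 10 and 15 without Young MMP high 2 and 3, 14, 9 and 9 without Old MMP high 1, 2 and 3, and 40 without Young MMP low 3. Calls were lost for Aldh1a1 without Young MMP high 1 or 2 or Old MMP high 1 or 2 (adjusted p from 0.0512 to 0.0793), for Rhoj without Young MMP high 2 or Old MMP high 2 or 3 (0.0591 to 0.0793), for Abca4 without Young MMP high 2 or Old MMP high 3 (0.0526 and 0.0773), for Ebi3 without any 1 old MMP high library (0.0852 to 0.125), and for Slc24a5 without any 1 MMP high library (0.0562 to 0.250).

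Old MMP high libraries lay at a root mean square distance of 0.783 ± 0.0424 (SD, n = 3) log2 CPM from the mean of the young libraries, and old MMP low libraries at 0.882 ± 0.0255 (n = 3). The difference of -0.0989 had an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3. Within the old pairs it was -0.163, -0.0948 and -0.0385 (exact sign-flip p = 0.25, the smallest possible with 3 pairs). Over 43 ageing genes outside the identity list the distances were 1.84 ± 0.117 and 2.73 ± 0.0893, a difference of -0.888 (exact p = 0.1), and over the 2000 most abundant genes the difference was -0.0338 (exact p = 0.5), and it was below 0 in only 1 of 3 pairs. The distance of a single library also holds the scatter within its group. Between libraries of 1 group, chi-square per degree of freedom of the counts was 42.6 to 74.6 in old MMP low HSCs. It was 24.5 to 40.2 in old MMP high HSCs, so scatter may add to the difference. The mean of all young libraries carries the MMP difference of young HSCs into the distance. Against young libraries of the same MMP (4 MMP high, 3 MMP low), the difference was -0.122 over all genes and -0.516 over the ageing genes, whose distances were 2.02 ± 0.157 and 2.54 ± 0.101 (exact p = 0.1 for both).

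Averaged over age, MMP high against low gave 1632 called genes, 827 higher and 805 lower. The higher genes of smallest p were Uhrf1 (2.17), Ncapd2 (1.82), Cdt1 (1.67), Brip1 (2.36) and Tuba8 (1.77), and the lower ones Sult1a1 (-2.79), Gbp4 (-2.58), Ifitm1 (-1.63), Gbp8 (-2.04) and Smtnl1 (-5.16), with edgeR adjusted p from 5.28e-05 to 5.5e-05. Slamf1 (-0.96) and Ly6a (-1.83) fell, and Abcg2, a dye efflux pump, fell by 0.48 (SE 0.12, adjusted p = 0.0209), in all 7 MMP high libraries, though its adjusted p was 0.0554, 0.0708 and 0.0883 without Old MMP low 2, Old MMP high 1 and Old MMP high 3. Of 35 replication genes 32 rose, 35 adjusted over the list alone (median 1.17, camera adjusted p = 1.26e-40, and adjusted p = 0.0118 with an estimated correlation). Of 35 identity genes 21 fell, 24 adjusted over the list alone (median -0.730, camera adjusted p = 3.85e-16, and adjusted p = 0.0119 with an estimated correlation). Of 47 ageing genes 20 fell, 29 adjusted over the list alone (median -0.827, camera adjusted p = 7.46e-12, and adjusted p = 0.0118 with an estimated correlation). Of 19 genes reported lower with ageing 6 rose, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00537, but adjusted p = 0.229 with an estimated correlation). Of 23 megakaryocyte genes 8 rose and 2 fell, 11 and 4 adjusted over the list alone (camera adjusted p = 0.00113, but adjusted p = 0.229 with an estimated correlation). Of 70 respiratory chain genes 4 rose, also 4 adjusted over the list alone (median 0.196, camera adjusted p = 1.43e-05, but adjusted p = 0.526 with an estimated correlation). Of 31 genes of the citric acid cycle and fatty acid oxidation 5 rose, also 5 adjusted over the list alone, but 14 lay above 0 (median -0.0115, camera upward, adjusted p = 0.231, and adjusted p = 0.664 with an estimated correlation). Of 32 biogenesis and import genes 6 rose, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000483, and adjusted p = 0.0170 with an estimated correlation). Of 36 G2 and mitosis genes 28 rose, 35 adjusted over the list alone (median 1.15, camera adjusted p = 2.9e-26, but adjusted p = 0.121 with an estimated correlation). Of 35 interferon genes 12 fell, with 3 higher and 22 lower adjusted over the list alone (median -0.567, camera adjusted p = 1.03e-06, and adjusted p = 0.0405 with an estimated correlation). The count of calls was 1010 without Old MMP low 2, 1047 without Old MMP high 2 and 976 without Old MMP high 3.

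Averaged over MMP, old against young gave 134 called genes, 112 higher and 22 lower. Nupr1 (2.09), Plscr2 (3.37), Selp (3.26), Clca1 (2.95) and Sbspon (5.81) rose (edgeR adjusted p from 1.27e-05 to 5.44e-05), and Rps4l (-1.55), Ebi3 (-1.52), Ctla2a (-1.13), Rnase6 (-1.46) and Slc24a5 (-2.58) fell (adjusted p from 0.000304 to 0.00427). Of 47 ageing genes 25 rose, 35 adjusted over the list alone (median 1.38, camera adjusted p = 3.66e-47, and adjusted p = 9.05e-05 with an estimated correlation). The count of calls was 75 and 74 without Old MMP low 2 and 3, and 89, 60 and 81 without Old MMP high 1, 2 and 3.

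No gene passed the test of the interaction of age and MMP by edgeR, which asks whether the MMP difference itself differs between young and old HSCs. At an unadjusted p of 0.05 there were 693 genes, DESeq2 called 2 and voom with quality weights 0. The smallest adjusted p was 1.00, and the genes of smallest p were Pomt1 (1.73), Rps4l (1.51), Hdac5 (1.63) and Nup62 (1.20) above 0 and Nupr1 (-1.13), Pcgf2 (-3.00) and Zmat2 (-1.03) below 0, with Prkcz, which had no count in young MMP low HSCs, given no fold. The replication list had a median of 0.581 (camera adjusted p = 7.28e-15, but adjusted p = 0.458 with an estimated correlation), with 8 genes higher adjusted over the list alone. The respiratory chain list had a median of -0.239 (camera adjusted p = 0.000283, but adjusted p = 0.927 with an estimated correlation, and 0.684, 0.0734 and 0.167 by camera without Young MMP low 2, Old MMP low 1 and Old MMP high 2) and the ageing list -0.230 (camera adjusted p = 0.0629). Without 1 library, the median of the ageing list ran from -0.317 to -0.109 and its camera adjusted p from 0.00382 to 0.304.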

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

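The test of progenitors outside the gate and the covariate for granulocyte transcripts were chosen only after the results were seen.

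Replication genes were higher in MMP high HSCs of both ages, and the difference was larger in old HSCs by 0.581, which is a candidate difference with age but was not called with an estimated correlation (adjusted p = 0.458). With the covariate for granulocyte transcripts, 29 of the 29 replication genes called in old HSCs stayed called, which argues against carry-over that follows these transcripts. Of all 627 genes called in this contrast 606 stayed called, so this is not particular to replication genes. Carry-over of cells that does not follow granulocyte transcripts was not tested. Progenitors outside the gate in the MMP high libraries stay open, since 2 of 3 markers (Flt3 at 1.26 ± 0.34, adjusted p = 0.0328 and up to 0.0884 without 1 library, and Cd34 at 0.58 ± 0.17, adjusted p = 0.0507) lay above 0 by more than 2 SE, while Cd48 was at -0.14 ± 0.51. The whole list of 12 progenitor genes points the other way, with 2 above 0 and a median of -0.770 (-0.583 in young and -1.13 in old HSCs), but it was not called (camera adjusted p = 0.260) and most of its other members are myeloid genes, which other myeloid cells of the marrow also express. The biological explanation, that HSCs of high membrane potential cycle more, may hold but was not tested.

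Among lists in the interaction of age and MMP, 4 others passed with the preset correlation: respiratory chain -0.239 (adjusted p = 0.927 with an estimated correlation), G2 and mitosis 0.562 (0.927), cytosolic ribosomal proteins -0.619 (0.907) and stromal markers 1.12 (0.805, and up to 0.205 by camera without 1 of 6 libraries, Old MMP high 1 the highest). In Young MMP high 3 the list of mitochondrial biogenesis lay below the other 3 libraries, with a gap of 0.883 of the range. In Young MMP high 4 Sult1a1 lay lowest, with a gap of 0.849 of the range (2.15 log2 CPM against 3.33 to 3.54). Chance marks about 1 in 20 groups in this way, and 43 genes, 33 lists and 8 measures were examined.

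Other splits of the same libraries were counted for each contrast. In young HSCs 1 of 35 splits called as many genes (170, with the highest other 44), and in the age contrast of MMP high HSCs 1 of 35 (25, with the highest other 0). This is the smallest share that 35 splits allow, and it argues against an arbitrary grouping of these libraries. It does not exclude chance, as replicates may be technical and a wrong split adds any real difference to the spread. The young splits also ignored neighbouring names, and a fit of the young libraries alone called 0 genes. In the averaged MMP contrast 1 of 100 splits called as many (1632, highest other 208), and in the averaged age contrast 1 of 100 (134, highest other 1). The real labels thus gave more calls than any other split drawn, with the same limits. These splits also ignored the possible pairs of old libraries. For MMP in old HSCs (627, highest other 0) and for age in MMP low HSCs (30, highest other 0), 1 of 10 splits called as many, and the splits are too few for a share under 0.05. In the old MMP contrast 4 of the splits part all 3 pairs, as the real split does, and the other 3 of these called 0 genes, like the splits that part fewer pairs. For the interaction the real count is 0, so 100 of 100 splits had to call as many, and this count decides nothing. The highest other split called 208 genes, which points to a structure of the samples: in it all old libraries exchange MMP labels and Young MMP low 3 exchanges with Young MMP high 3, so it tests the averaged MMP difference with that 1 exchange.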

How the results depend on the processing

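The carry-over covariate, the fit without 2 doubted libraries and the block for old pairs were chosen after the data were seen. Of named genes under all alternatives, 14255 comparisons kept direction and side of the threshold, 149 passed it newly, 636 no longer passed and none reversed. Of lists, 3578 stayed, 111 passed newly, 233 no longer passed and 5 reversed. The cause was not tested, except that fewer libraries enter a fit of only 2 groups or one without a library.

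For MMP in young HSCs, calls went from 170 to 756 without a filter, 810 with DESeq2, 0 with only the 2 groups, 342 with a replicate block, 443 with the carry-over covariate and 369 without 2 doubted libraries, and from 11 to 275 without 1 library. For MMP in old HSCs they went from 627 to 1190 without a filter, 1316 with DESeq2, 1486 with voom weights and 1008 without 2 libraries (223 to 818 without 1 library). For age they were 204, 197 and 18 (no filter, DESeq2, voom weights) in MMP low HSCs (10 to 46 without 1 library) and 211, 150, 155 and 49 with the covariate in MMP high HSCs (9 to 40). The averaged MMP contrast had 2580 with DESeq2 (976 to 1825), the averaged age contrast 410 without a filter and 430 with DESeq2 (60 to 142), and the interaction 58 without a filter and 2 with DESeq2. In the self-test, whose counts were drawn with edgeR's own dispersions, DESeq2 made 35 wrong calls of 130 in the old MMP contrast, against 4 of 66 for edgeR. The correlation of young and old fold changes was 0.688 over the more abundant genes and 0.136 to 0.400 without 1 library.

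In MMP low HSCs the age median of the respiratory chain was 0.204 without Young MMP low 1 (range -0.209 to 0.204), that of G2 and mitosis 0.210 without Old MMP low 2 (-0.633 to 0.210), and that of cytosolic ribosomal proteins -0.0144 without Young MMP low 2 and -0.0213 without Old MMP low 1 (to 0.389). In the interaction the granulocyte list was at -0.424 (camera upward, adjusted p = 0.927), and at -0.664 with a replicate block (camera downward, 0.0167, against 0.0596 to 0.980 under the other alternatives). A name-pair block could not be fitted for the age contrasts. In the self-test few 2-fold changes were found in the contrasts within 1 age or 1 MMP group and in the interaction, and more in the averaged contrasts. Added after the data were seen were the exact sign-flip test of the distance within the old pairs (p = 0.25) and the distance to young libraries of the same MMP.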

Other observations

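The tests of granulocyte against B cell markers, of library pairs nearest in total counts and of library names, the covariate and the comparison with young HSCs were chosen only after the results were seen.

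Averaged over age, chromatin genes moved both ways with MMP. The maintenance methyltransferase Dnmt1 (1.30 ± 0.17, edgeR adjusted p = 0.000461) and Ezh2 of the Polycomb complex (0.96 ± 0.17, 0.00356) rose in MMP high HSCs, while Ezh1 (-1.18 ± 0.16, 0.000570) and Cbx7 (-1.23 ± 0.26, 0.0102) fell. Of 26 chromatin genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; median -0.0151, though camera pointed up, adjusted p = 0.945). Of 23 antioxidant genes Gclm (0.40) was among 2 that rose and Gstm1 (-1.49), Srxn1 (-0.82) and Nfe2l2 (-0.56) were among 4 that fell (3 and 4 adjusted over the list alone; median 0.0508, camera downward, adjusted p = 0.788). Of 27 mitophagy and autophagy genes, Map1lc3b (-0.68), Lamp2 (-0.62) and Bnip3l (-0.47) fell (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0141, but adjusted p = 0.303 with an estimated correlation, and 0.0525 and 0.0649 by camera without Young MMP low 1 and Old MMP high 1). The calls of Bnip3l and Gclm were lost without 10 and 6 of the libraries in turn (adjusted p up to 0.164 and 0.0738). Of 20 glycolysis genes, Tpi1 (0.45) and Pgk1 (0.51) rose, and Ldhb (-0.91) and Aldoa (-0.54) were among 3 that fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.964). Cd74 (-2.07) and Birc3 (-0.73) were among 5 of 23 inflammatory genes that fell, with 2 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0224, but adjusted p = 0.229 with an estimated correlation, and 0.0501 and 0.0649 by camera without Young MMP low 1 and Old MMP high 1). Sesn1 (-0.99) and Plk2 (-1.44) of 18 p53 and senescence genes fell, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.231, and adjusted p = 0.406 with an estimated correlation).

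Other lists of the averaged MMP contrast are given by their camera adjusted p and, after it, the adjusted p with an estimated correlation. These were 0.000483 and 0.397 for mitochondrial ribosomal proteins, 0.570 and 0.690 for efflux transporters, 0.964 and 0.978 for lymphoid priming, 0.260 and 0.690 for multipotent progenitors, and 0.788 and 0.978 for cytosolic ribosomal proteins. They were 0.000147 and 0.201 for Myc and ribosome biogenesis, 0.0632 and 0.147 for transcription machinery, 4.17e-08 and 0.0414 for the spliceosome, 0.00906 and 0.664 for immediate early genes (0.147, 0.0698 and 0.121 by camera without Young MMP low 3, Old MMP low 2 and Old MMP high 1), and 0.680 and 0.837 for heat shock genes. Among cell markers they were 0.00906 and 0.664 for granulocyte and monocyte genes (median -0.885, none of 19 above 0), 0.448 and 0.837 for erythroid (median -0.268, camera upward), 0.680 and 0.971 for B cell, 0.432 and 0.690 for T and NK cell, and 0.0520 and 0.229 for stromal genes. They were 0.000441 and 0.519 for histones and 0.0224 and 0.229 for sex-linked genes. With 1 library left out, the spliceosome median ran from 0.310 to 0.476 and that of histones from 0.830 to 1.24. Those of mitochondrial ribosomal proteins (0.141 to 0.249) and of Myc and ribosome biogenesis (0.226 to 0.305) also stayed above 0. Medians of immediate early genes (-0.364 to -0.186) and sex-linked genes (-0.668 to -0.438) stayed below 0. Median, mean and camera direction differed in sign for the citric acid cycle, glycolysis, antioxidant, cytosolic ribosome, heat shock, chromatin and erythroid lists.

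Mature blood cell transcripts varied between libraries of 1 group, and the deviations of granulocyte and B cell markers moved together (r = 0.893, permutation p = 0.00198, adjusted p = 0.00495 over 5 relations; rho 0.824, p = 0.00516; r = 0.822 without the 2 farthest libraries). Erythroid markers also moved with the granulocyte markers (r = 0.897, permutation adjusted p = 0.00495). T and NK cell markers did so less clearly (r = 0.663, permutation adjusted p = 0.0969, and r = 0.413 without the 2 farthest libraries). For the log2 number of genes with a count, r was 0.550 (permutation adjusted p = 0.0969, and r = 0.486 without the 2 farthest libraries). Carry-over of mature marrow cells or their RNA may explain the joint movement of the markers. A part that follows the number of genes with a count stays open. Depth as the whole source is argued against: total counts ranged over 1.24-fold, and in the 5 of 15 library pairs of 1 group nearest in total counts the granulocyte score differed by a median of 2.57, against 1.87 in the other 10 (ratio 1.37, at least 1.16 without any 1 library). A part that follows depth stays open (r = 0.272, permutation p = 0.435, and r = 0.0458 without 2 libraries), and so does a source shared by libraries with neighbouring names, as 9.03% of 144 pairings differed as little. No biological explanation was tested.

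Ageing genes were lower in MMP high than in MMP low old HSCs. Genes shared with the identity list are argued against as the whole source, since the 43 others had a median of -1.05. Only 4 of the 47 genes are shared, so leaving them out could hardly move the median. With the covariate, 11 of the 11 called genes stayed called, which argues against carry-over that follows granulocyte transcripts. Of all 627 genes called in this contrast 606 stayed called, so this is not particular to ageing genes. A change found only in old HSCs is argued against by the median of -0.592 in young HSCs (adjusted p = 0.0417 with an estimated correlation, 0.0618 without the shared genes). That membrane potential goes with a less aged expression pattern may be the biological explanation, and it stays untested.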
